A study of Mus musculus with 10 samples.

How the data were processed

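Total RNA was taken from mouse bone marrow cells with a column kit and DNase treatment, ribosomal RNA was removed with RNase H, and libraries were sequenced on an Illumina sequencer, per the labels. The authors' notes name bcl2fastq and DRAGEN, without versions or roles, and the genome build GRCm38. The annotation release, the quantifier and the strand setting are not given in the sources used here. The deposited table holds expected counts (expected_counts) per gene, unscaled between libraries, and 10.3% of its values are not whole numbers.

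All 10 libraries were used, 5 per group, and no comparison other than α-KG against water follows from the labels. No paired analysis was possible because the sample titles carry different numbers in the groups and no label pairs them. Counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR with its default minimum count of 10 and minimum total of 15, which left 15126 of the 32256 genes with a count above 0 in some library; they held at least 99.8% of the counts of each library. Library totals ran from 14291364 to 22490118, and the common biological coefficient of variation was 0.254. The median log2 fold change of all tested genes was 0.02.

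Genes were tested with the quasi-likelihood F test of edgeR 4.0.16 (TMM scaling, robust dispersion, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. Printed errors of log2 fold changes are standard errors, taken as the absolute log2 fold change divided by the square root of F. Values in CPM are counts scaled to a library of 1e+06 counts after TMM normalisation, and are given with their SD. The same steps were tested on simulated data of 15126 genes with 200 changed in each of 5 simulations. There, 6.13% of the calls were false, a planted list was called in all 5 simulations and 0 of 100 unchanged lists were called by camera. Simulated genes varied independently of each other, so these list counts do not measure camera's false calls in the real libraries, where 69 of 100 splits, the real one included, gave at least as many lists as the real one.

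The model, the tests, 30 gene lists, the rule for named genes and most of the alternatives were chosen before the data were examined. The rule took the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 0 and all 5 values of a group on the same side of the other group's mean, leaving out unnamed gene models and immune receptor segments. It also took the 3 members with the smallest unadjusted p of each list described gene by gene, and 20 fixed genes. Some genes that these rules took are not reported here. Genes called in a list are said to rise or fall only where they pass over all genes tested, or where the adjustment over the list alone is named.

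Lists with at least 5 measured members were tested with camera of limma 3.58.1 at its preset correlation of 0.01 and adjusted over the 30 lists, then with the correlation estimated from the data and with fry, whose p tests whether a list's genes move on balance in 1 direction and does not compare the list with other genes. List means per library were taken over log2(CPM + 1), and 13 cell type lists were compared by exact two-sided permutation tests over the 252 assignments of 5 and 5 libraries, whose smallest p is 0.00794. Principal components used log2 CPM with a prior count of 2. Shares of library composition were compared by the same exact test over 11 measures.

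Alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma voom with and without quality weights), a surrogate variable (sva 3.50.0), list means or composition as covariates, and each library left out in turn. A sex covariate was not fitted, because Xist and Y-linked transcripts were found together in every library. Whether this came from mixed sexes, transplanted marrow or RNA carried between samples was not tested, so what a single library stands for among the 5 of a group is not known here. Gene positions, biotypes, GC content and length came from GENCODE M21 on GRCm38, where 53292 of the 55367 symbols were found; 1 list member was looked up through a synonym, and Fam177a2 was not found, so its position is not given.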

Results

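RNA was sequenced from bone marrow cells of mice, labelled BMMC, to compare animals given 1% α-ketoglutarate (α-KG) in the drinking water with animals given regular water. α-KG is an intermediate of the tricarboxylic acid (TCA) cycle and a co-substrate of many dioxygenases. The series title concerns metabolism, platelet activity and inflammation in myeloproliferative neoplasms, blood disorders with an excess of myeloid cells. Each group held 5 libraries, named here water 1 to 5 and α-KG 1 to 5, and the shared numbers pair nothing. Genotype, sex and length of treatment are not given in the sources used here. The labels do not say that each library came from its own animal, so p-values measure the spread between these libraries.

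The deposited table held estimated counts for 55367 genes. Totals in the water libraries were 22490118, 21830425, 21461132, 20352745 and 16938450, and those in the α-KG libraries were 18955177, 21489380, 19930225, 14291364 and 17017038. Between 21563 and 24117 genes had a count above 0 in a library. Transcripts of Xist, which is expressed from an inactive X chromosome, reached 258 to 785 CPM and those of the Y-linked gene Ddx3y 13.5 to 28.0 CPM over all 10 libraries. Differences between libraries of a group exceeded counting error, with a chi-square per degree of freedom of 34.8 to 457 for pairs of libraries within a group. On simulated counts of this depth and spread, the test recovered 8.66% of changes of 1.5-fold, 55.5% of changes of 2-fold and 89.1% of changes of 4-fold. Only 200 genes and a planted list were changed there and genes varied independently, so these rates do not measure recovery in the real libraries.

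A large part of the counts came from small non-coding RNAs. Rn7s1 and Rn7s2, copies of the RNA of the signal recognition particle, took 16.4% ± 5.92 of the counts in water and 27.2% ± 2.50 in α-KG (SD, n = 5; exact permutation p = 0.0159, adjusted p = 0.0582 over 11 composition measures). Histone cluster genes took 1.12% ± 0.343 in water and 0.560% ± 0.187 in α-KG, and the groups did not overlap (SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.0437). Symbols not matched to the annotation used took 1.83% ± 0.408 in water and 1.08% ± 0.312 in α-KG, also without overlap (SD, n = 5; exact permutation p = 0.00794, adjusted p = 0.0437). Histone genes were taken by symbol and these by annotation match, so the same counts can be in both shares. Unmatched symbols were not counted as protein-coding. Protein-coding genes took 55.7% ± 10.9 in water and 46.0% ± 4.70 in α-KG (SD, n = 5; exact permutation p = 0.0873, adjusted p = 0.240). The share of CT010467.1, a locus of ribosomal RNA, ran from 3.67% to 21.1%, with means of 11.1% ± 5.87 in water and 10.7% ± 6.30 in α-KG (SD, n = 5; exact permutation p = 0.913, adjusted p = 0.913).

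**Figure D1:**
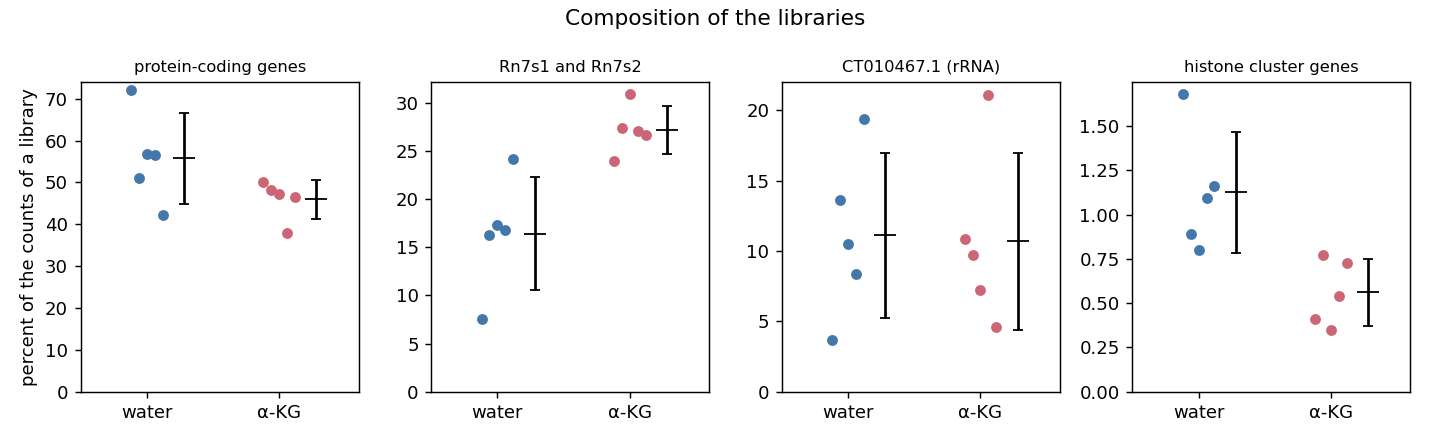
Percent of each library's counts in protein-coding genes, in Rn7s1 and Rn7s2, in the ribosomal RNA locus CT010467.1 and in histone cluster genes, with 1 point per library and bars at the mean ± SD of 5 libraries. The histone shares of the α-KG libraries, at most 0.774%, all lie below those of the water libraries, at least 0.7999%.

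With edgeR, more genes were called higher than lower in marrow cells of mice given α-KG. Of 15126 genes tested, 361 rose and 52 fell (edgeR, adjusted p under 0.05). Of these, 344 and 36 were protein-coding by the annotation used, which leaves out unmatched symbols. The median log2 fold change was 0.92 among those that rose and -1.005 among those that fell, and 153 and 28 of them changed at least 2-fold. The 5 libraries of each group did not overlap for 286 of these 413 genes (69.2%) and for 855 of all genes tested (5.65%), where chance gives 0.794% on average. The 413 genes were selected in these same libraries, so their lack of overlap is no separate support. Genes that vary together can also lift the share over all genes above 0.794% by chance. DESeq2, with its own scaling and filter, called 1657 genes, of which 969 were higher and 688 lower, so the share that rose was 58.5% against 87.4% with edgeR, and without α-KG 2 it called 1800 higher and 1816 lower. The edgeR count was 0 without water 1, water 2, water 4 or α-KG 4, with 3232 to 3672 genes still at an unadjusted p under 0.05 and 497 to 653 called by DESeq2, and it was 37 without α-KG 3, 72 without water 5, 139 without α-KG 1, 149 without α-KG 5, 632 without water 3 and 2683 without α-KG 2. It was also 0, with 3457 genes at an unadjusted p under 0.05, once the protein-coding share of the counts was a covariate, and all 413 genes kept their sign in each of these fits.

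The largest rises among the genes named by the fixed rule included enzymes and secreted proteins. Hpgd, which encodes the enzyme that inactivates prostaglandins (chromosome 8, 56294585 to 56321043, build GRCm38), went from 0.234 ± 0.152 CPM to 1.93 ± 0.766 (SD, n = 5; log2 fold change 2.96 ± 0.49 SE, adjusted p = 0.0172). Ace, encoding angiotensin-converting enzyme (chromosome 11, 105967945 to 105989964), went from 3.63 ± 1.09 to 18.0 ± 8.90 CPM (2.29 ± 0.33, adjusted p = 0.0154). Hmox1, encoding the haem-degrading enzyme haem oxygenase 1 (chromosome 8, 75093621 to 75100589), went from 9.93 ± 1.999 to 38.8 ± 17.3 CPM (1.96 ± 0.29, adjusted p = 0.0154). The matrix proteoglycan gene Vcan (chromosome 13, 89655312 to 89742509), which the antisense gene Gm4117 overlaps, went from 8.40 ± 4.21 to 44.5 ± 30.3 CPM (2.39 ± 0.52, adjusted p = 0.0387). With the monocyte mean as a covariate, Vcan stood at -0.12. The chemokine gene Cxcl12 (chromosome 6, 117168535 to 117181367) and Kitl, the gene of the ligand of the receptor Kit, rose by 1.85 ± 0.30 (adjusted p = 0.0172) and 1.99 ± 0.42 (adjusted p = 0.0328) on the log2 scale. Fstl1, Pgap1, Epb41l3 and Rgmb completed the 10, at log2 fold changes of 1.82 to 2.60 and adjusted p of 0.0154 to 0.0488. The water and α-KG libraries overlapped for Vcan, Fstl1 and Pgap1 and were apart for the other 7. Among the α-KG libraries, α-KG 2 was the lowest for all of the 10 except Hpgd and Epb41l3.

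Among the 10 largest falls, Gnb3, encoding a β subunit of G proteins (chromosome 6, 124834240 to 124840275), went from 1.52 ± 0.363 CPM to 0.386 ± 0.263 (SD, n = 5; log2 fold change -2.05 ± 0.48 SE, adjusted p = 0.0443). The transcription factor gene Nfe2l3 (chromosome 6, 51432670 to 51458768) went from 3.98 ± 2.14 to 1.39 ± 0.308 CPM (-1.54 ± 0.33, adjusted p = 0.0354). The ephrin receptor gene Epha10 fell by 1.90 on the log2 scale (adjusted p = 0.0257). Olfactory receptor genes Olfr68 and Olfr543 had log2 fold changes of -1.66 and -1.49 (adjusted p = 0.0433 and 0.0154). Olfr68 ends at position 103779698 of chromosome 7 and the globin gene Hbb-bt starts at 103812524. Gpr161, Nkpd1, Dnd1, Fam177a2 and Tmem184a made up the rest of the 10, with log2 fold changes of -1.47 to -1.13 and adjusted p of 0.0172 to 0.0422. Among the water libraries, water 1 was the highest for all of the 10 except Olfr68. Nfe2l3, for example, was at 7.57 CPM in water 1 and at 2.48 to 4.37 in the other water libraries. All 10 had groups that did not overlap. On the opposite strand, Dnd1 overlaps Wdr55 and Tmem184a overlaps Mafk, and the strand setting of the counting is not given in the sources used here.

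**Figure D2:**
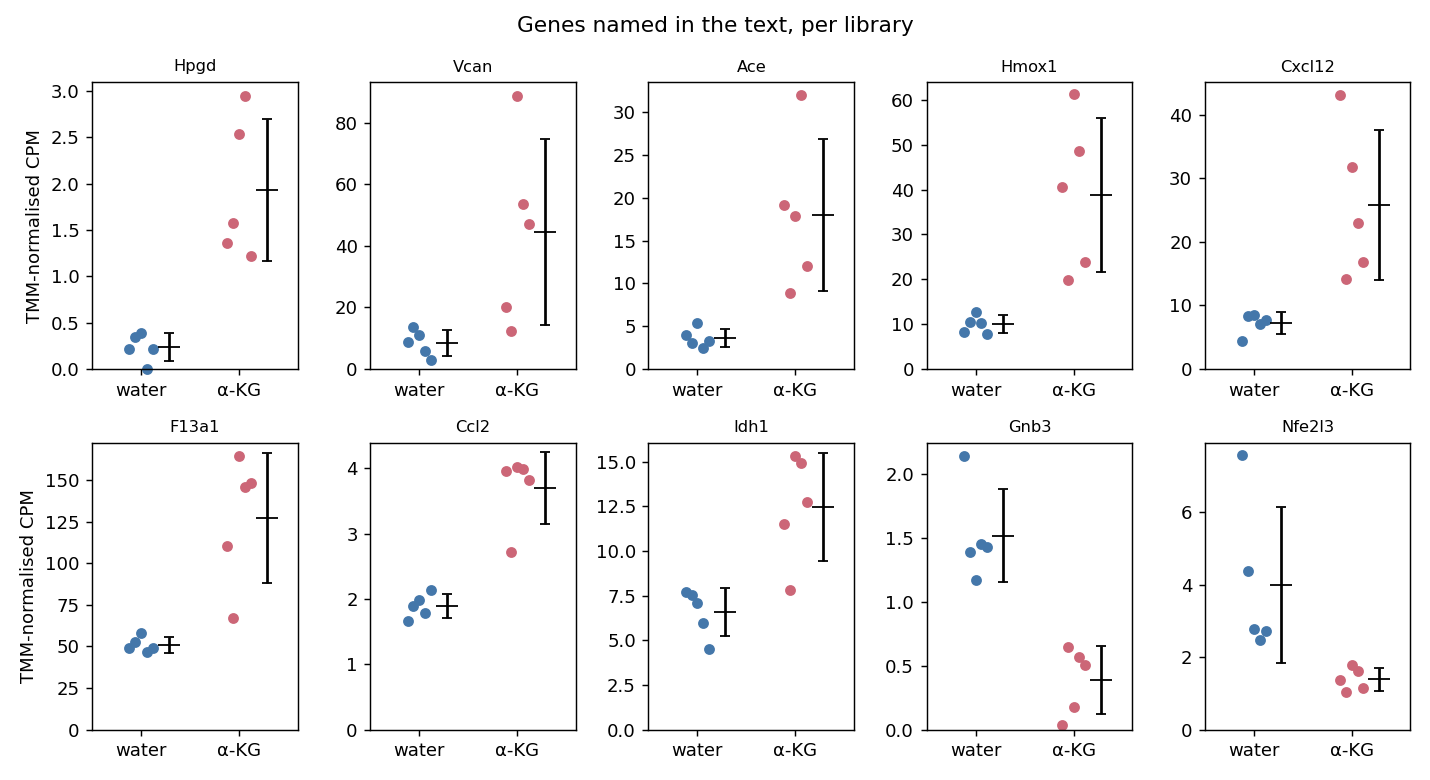
TMM-normalised CPM of 10 genes named in the text, with 1 point per library and bars at the mean ± SD of 5 libraries. Vcan is the gene plotted whose groups overlap, and Gnb3 and Nfe2l3 are lower in the α-KG libraries.

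Most monocyte and macrophage genes were at higher levels in α-KG, with 15 of 16 and 14 of 15 log2 fold changes above 0. Of 16 measured monocyte genes, 9 rose over all genes tested and 14 rose adjusted over the list alone, with a median log2 fold change of 1.03. F13a1, which encodes a subunit of clotting factor XIII, went from 51.0 ± 4.67 to 127 ± 39.0 CPM, and the lysosomal protease gene Ctss from 34.3 ± 6.94 to 75.3 ± 15.8 CPM (SD, n = 5; log2 fold changes 1.32 and 1.13, both with adjusted p = 0.0154). Ctss was lower in α-KG 2 than in the other α-KG libraries, and Mrc1 was higher in water 3 than in the other water libraries. Of 15 measured macrophage genes, 7 rose over all genes tested and 14 rose adjusted over the list alone, with a median of 1.03. With Hmox1, they included the mannose receptor gene Mrc1 (log2 fold change 1.47 ± 0.22 SE) and the receptor kinase gene Axl (1.35 ± 0.22), both with adjusted p = 0.0154. Both lists ranked above other genes (camera with its preset correlation, adjusted p = 4.53e-13 for each), a call that was lost at an adjusted p = 0.423 with an estimated correlation. With fry, the adjusted p was 0.0248 for the monocyte and 0.0209 for the macrophage list.

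Genes of T and NK cells were also at higher levels. All 19 measured members had log2 fold changes above 0, with a median of 0.77, of which 2 rose over all genes tested and 10 rose adjusted over the list alone. The interleukin 2 receptor gene Il2rb rose by 0.78 ± 0.18 SE (adjusted p = 0.0404) on the log2 scale. Cd3e, part of the T cell receptor complex, rose by 1.12 ± 0.26 (adjusted p = 0.0445). Gzma was at 1.94 ± 0.55 (adjusted p = 0.0702), with 5.04 CPM in α-KG 4 and 0.544 to 1.51 in the other α-KG libraries. The list was called by camera (adjusted p = 3.29e-06) and had an adjusted p = 0.862 with an estimated correlation and 0.112 with fry.

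Per library, the macrophage list mean was 0.87 higher in α-KG on the log2(CPM + 1) scale (n = 5 per group, exact permutation p = 0.00794, the smallest possible), the monocyte mean 0.81 higher (exact permutation p = 0.0159) and the T and NK mean 0.49 higher (exact permutation p = 0.0159). None of the 13 cell type lists passed after adjustment (smallest adjusted p = 0.0688), against 3 at an unadjusted p under 0.05. B cell, plasma cell, neutrophil, granulocyte precursor, platelet, stem cell, basophil, stromal and skeletal muscle means differed by -0.09 to 0.24 (exact permutation p = 0.0952 to 0.833).

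Cell cycle genes were lower in α-KG. All 33 measured members had log2 fold changes below 0, with a median of -0.70; 0 fell over all genes tested and 32 fell adjusted over the list alone. Cdk1, the kinase that drives entry into mitosis, went from 52.4 ± 4.41 to 29.9 ± 10.5 CPM (SD, n = 5; log2 fold change -0.81 ± 0.20 SE, adjusted p = 0.0555). The mitotic genes Ccnb2 and Tpx2 were at -1.02 ± 0.29 (adjusted p = 0.0690) and -0.81 ± 0.25 (adjusted p = 0.0794), and water 3 lay below the other water libraries for Cdk1 and Tpx2. The list was called by camera (adjusted p = 1.48e-15) and had an adjusted p = 0.862 with an estimated correlation and 0.112 with fry. Its mean per library was 0.77 lower in α-KG (n = 5 per group, exact permutation p = 0.0159, adjusted p = 0.119 over 30 lists).

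Erythroid genes had a median log2 fold change of -0.55 over 24 measured members, with 0 passing over all genes tested or adjusted over the list alone. Ermap, Rhag and the erythropoietin receptor gene Epor were at -0.96 ± 0.44, -0.96 ± 0.49 and -0.88 ± 0.44 (SE; adjusted p = 0.176 to 0.220), whereas the globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt were at 0.36 to 0.54. The call by camera (adjusted p = 0.0124, and 0.891 with an estimated correlation) ended without α-KG 1. That library had an erythroid mean of 7.36 on the log2(CPM + 1) scale, where the other α-KG libraries had 9.25 to 9.93.

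**Figure D3:**
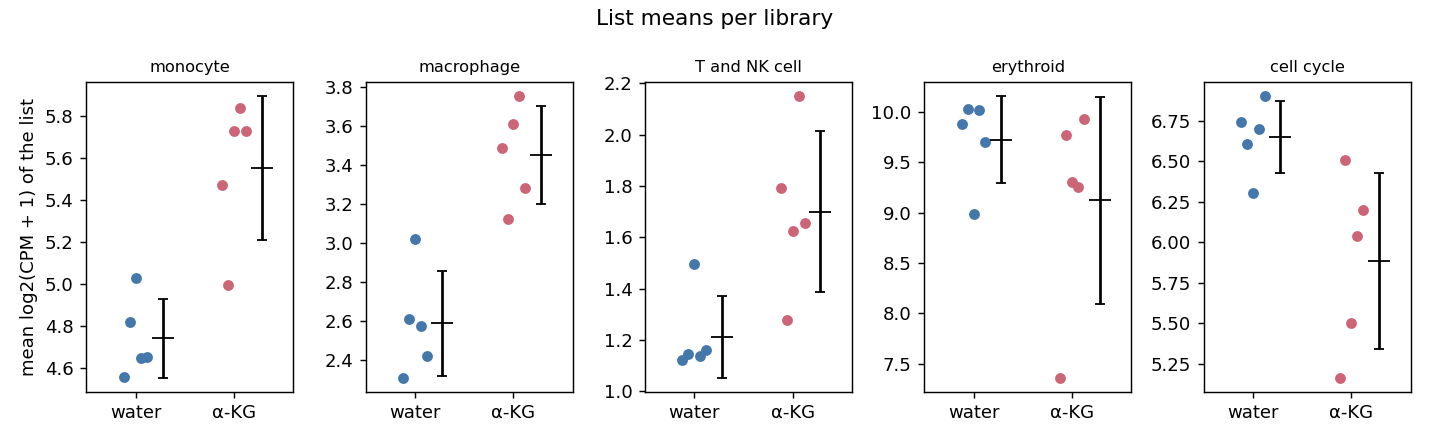
Mean log2(CPM + 1) over the measured members of the monocyte, macrophage, T and NK cell, erythroid and cell cycle lists, with 1 point per library and bars at the mean ± SD of 5 libraries. The macrophage means of the α-KG libraries lie above those of the water libraries, and the lowest erythroid mean is that of α-KG 1, at 7.36.

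Few inflammatory and interferon genes passed over all genes tested, with 12 of 21 and 20 of 26 log2 fold changes above 0. Of 21 measured inflammatory genes, 2 rose over all genes tested and 6 rose adjusted over the list alone. Both were chemokine genes: Ccl2, which recruits monocytes (chromosome 11, 82035571 to 82037453), went from 1.89 ± 0.184 to 3.70 ± 0.556 CPM (SD, n = 5; log2 fold change 0.97 ± 0.17 SE, adjusted p = 0.0216), and Ccl4 rose by 1.04 ± 0.23 (adjusted p = 0.0404) on the log2 scale. Ccl5 was at 1.99 ± 0.58 (adjusted p = 0.0735), with 24.8 CPM in α-KG 4 and 1.68 to 9.93 in the other α-KG libraries. The cytokine genes Il1b, Tnf, Il6 and Cxcl2 were at -0.07, -0.01, 0.80 and -0.13, with adjusted p of 0.203 to 0.977. Of 26 measured genes of the type I interferon response, 1 rose over all genes tested, Trim30a (0.74 ± 0.17, adjusted p = 0.0450), and 8 rose adjusted over the list alone, while Ddx58 and Zbp1 were at 0.54 and 0.95 (adjusted p = 0.0554 and 0.0597). Ccl2 and Trim30a were lower in α-KG 2 than in the other α-KG libraries, and with the monocyte mean as a covariate Ccl4 and Trim30a stood at -0.03 and -0.01. Camera called both lists (adjusted p = 0.0305 and 0.0176, each 0.891 with an estimated correlation), the inflammatory call ended without water 1, water 4, water 5, α-KG 1, α-KG 3 or α-KG 4, and the interferon call ended without α-KG 4 or α-KG 5.

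In each list of genes that handle α-KG, 1 member rose over all genes tested, where 413 of all 15126 genes tested were called. Such single calls do not show that these lists differ from other genes. Idh1, encoding the cytosolic isocitrate dehydrogenase that makes α-KG (chromosome 1, 65158616 to 65186500), went from 6.56 ± 1.34 to 12.5 ± 3.03 CPM (SD, n = 5; log2 fold change 0.91 ± 0.20 SE, adjusted p = 0.0364). Idh1 was the 1 of 25 measured members of the TCA cycle list that rose, and that list also holds cytosolic enzymes outside the cycle. Pcx and Dlat were at -0.92 and 0.40 (adjusted p = 0.141 and 0.135), Idh2 at 0.31 (adjusted p = 0.191) and Ogdh at -0.14 (adjusted p = 0.523). Glud1, the glutamate dehydrogenase gene that links glutamate and α-KG (chromosome 14, 34310727 to 34345265), went from 40.7 ± 6.12 to 63.5 ± 9.26 CPM (0.64 ± 0.14, adjusted p = 0.0386) and was the 1 of 18 measured genes of α-KG and glutamate interconversion that rose. Gpt and Slc25a11 were at -0.61 and 0.28 (adjusted p = 0.119 and 0.144). Of 35 measured α-KG-dependent dioxygenase genes, 1 rose, the collagen lysyl hydroxylase gene Plod3 (0.58 ± 0.12, adjusted p = 0.0344), which overlaps Znhit1 on the opposite strand. Over 28 alternatives, the lowest log2 fold changes of Idh1, Glud1 and Plod3 were 0.12, 0.10 and 0.17. Their calls were lost in 15, 14 and 14 of these alternatives. Riox2, Fto and Tet2 were at 0.47, 0.35 and 0.49 (adjusted p = 0.0838 to 0.102) and Egln3 at 0.19 (adjusted p = 0.441). Ndrg1, a target of hypoxia-inducible factor, was the 1 of 24 measured glycolysis and HIF target genes that rose over all genes tested (0.67 ± 0.16, adjusted p = 0.0452), beside 2 adjusted over the list alone, and stood at -0.03 with the monocyte mean as a covariate. Hk2 and Pdk1 were at 0.51 and -0.44 (adjusted p = 0.0584 and 0.139). In the TCA cycle, interconversion and dioxygenase lists, 1 member each rose adjusted over the list alone, and camera called none of these 4 lists (adjusted p = 0.229 to 0.732).

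Platelet and megakaryocyte genes gave 0 calls over all genes tested and 4 rises adjusted over the list alone among 29 measured members (edgeR), with a median log2 fold change of 0.22 (camera adjusted p = 0.295). The platelet tubulin gene Tubb1, the platelet basic protein gene Ppbp and the lipoxygenase gene Alox12 were at 1.09 ± 0.28, 0.82 ± 0.21 and 1.05 ± 0.30 (SE; adjusted p = 0.0584, 0.0577 and 0.0703). Pf4, Itga2b and Selp were at -0.33, 0.27 and -0.03 (adjusted p = 0.191 to 0.942). Jak2, the kinase gene often mutated in myeloproliferative neoplasms, was at -0.27 (adjusted p = 0.329).

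Of the stem and progenitor cell genes, 1 of 14 rose, the transcription factor gene Gata2 (log2 fold change 1.04 ± 0.24 SE, adjusted p = 0.0448), also the 1 adjusted over the list alone, and Meis1 and Ly6a were at 0.61 and 0.71 (adjusted p = 0.0970 and 0.191). Of 12 measured stromal genes, Cxcl12, Kitl and the apolipoprotein gene Apoe (1.06 ± 0.18, adjusted p = 0.0172) rose. Adjusted over the list alone, 3 rose and 2 fell. Col1a1, also in this list, had a log2 fold change below 0, given in the closing section. Both lists had a camera adjusted p = 0.0728. Of 19 immediate early and heat shock genes, which respond to handling of tissue, 1 rose, Nr4a1 (0.75 ± 0.17, adjusted p = 0.0404). Nr4a1 was also the 1 adjusted over the list alone, and it is among the genes of nonclassical monocytes tested below. Dnajb1 and Hspa1b were at -0.48 and -0.92 (adjusted p = 0.0901 and 0.0961).

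Camera called 11 of the 30 lists in all, 6 higher and 5 lower, with 0 called once the correlation was estimated and 2 by fry. Besides those above, these were the mitochondrially encoded genes of oxidative phosphorylation (median log2 fold change 0.84 over 13 genes, adjusted p = 0.00284), its nuclear genes (-0.18 over 65, adjusted p = 0.00659), cytosolic ribosomal proteins (-0.22 over 61, adjusted p = 0.000237) and ATF4 targets of the amino acid stress response (-0.50 over 19, adjusted p = 0.00373). Each had an adjusted p = 0.891 with an estimated correlation, and 0 of their members passed over all genes tested or adjusted over the list alone in edgeR. The nuclear list was no longer called without water 5 or α-KG 1. The mitochondrially encoded list was not called with the protein-coding share as a covariate, where its median was 0.15, and its median was 0.46 without α-KG 4; the nuclear, ribosomal and ATF4 lists were not called with the erythroid mean as a covariate. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 69 gave at least 11 lists. The remaining lists were not called (camera adjusted p = 0.291 to 0.777), among them late neutrophil granule genes, where S100a8 and S100a9 were at -0.13 and -0.00. Adjusted over the list alone, 2 granulocyte precursor genes rose, 4 skeletal muscle genes rose and 1 fell. Signs of the median, mean and test differed for the granulocyte precursor and plasma cell lists.

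**Figure D4:**
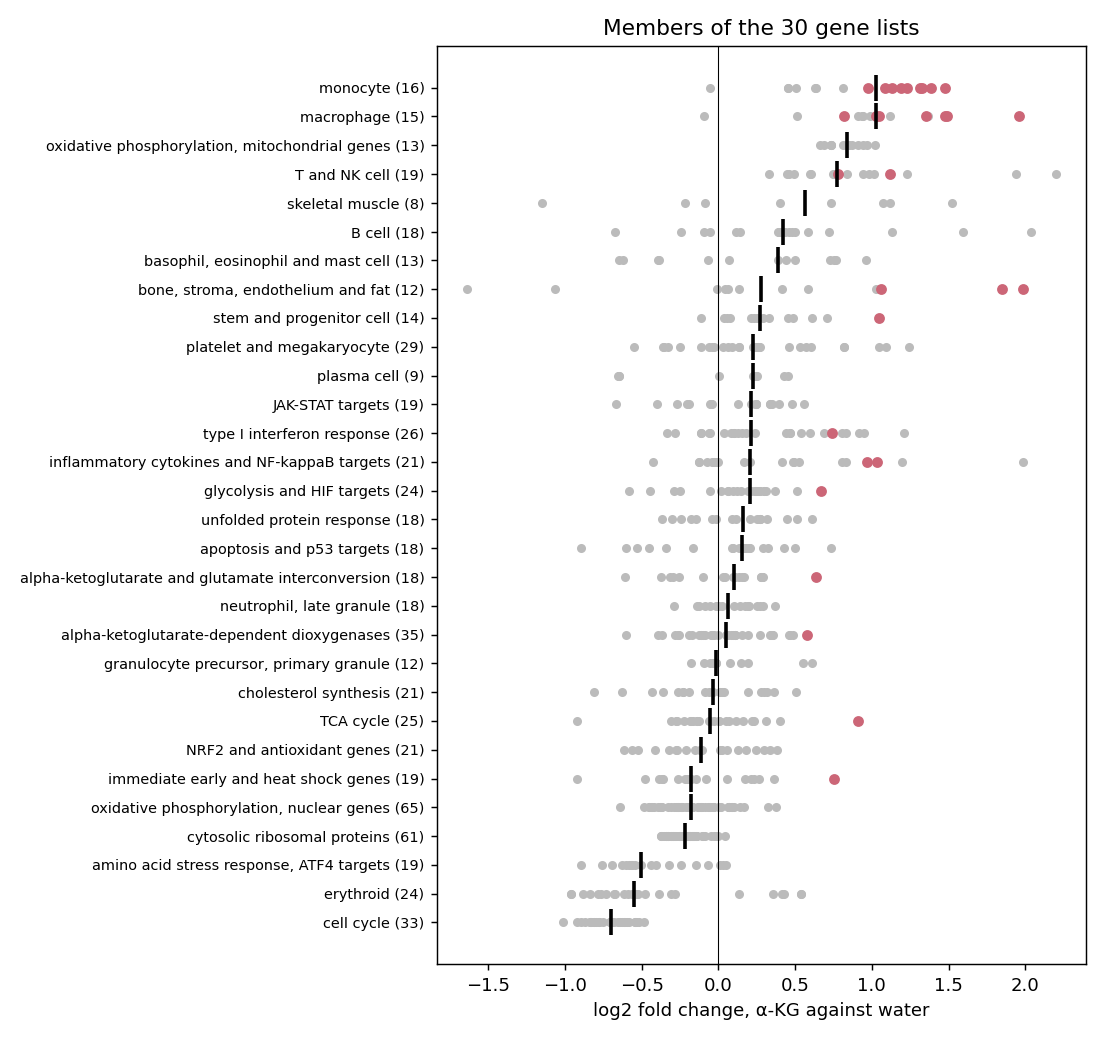
Log2 fold change, α-KG against water, of each measured member of the 30 gene lists, with the number of members after each name, black bars at the medians and coloured points for members past the adjusted p over all genes tested. The macrophage and monocyte lists hold 7 and 9 coloured points, and the members of the cell cycle list all lie below 0.

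The first principal component of the 1000 most variable genes held 44.4% of their variance. Its mean was -15.2 ± 7.31 in water and 15.2 ± 26.7 in α-KG (SD, n = 5; exact permutation p = 0.0317, adjusted p = 0.0635 over both components), with α-KG 1 farthest out at 53.3. α-KG 2 and α-KG 5, at -12.0 and -7.85, lay within the range of the water libraries, -20.9 to -2.73. The adjusted p of this component was 0.0317 without α-KG 1, α-KG 2 or α-KG 5. The second component held 12.6% of the variance and did not separate the groups (exact permutation p = 0.183, adjusted p = 0.183).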

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

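The tests of Lars2 were chosen only after its values were seen. In each group of 5 libraries, the lowest or highest value was compared with the rest, and it counted as far away when its gap to the nearest other value exceeded 0.71 of the group's range (Dixon's test). This held for 20 of 282 groups of values, where chance gives about 1 in 20. All levels below are log2(CPM + 1).

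Among list means, α-KG 1 had an erythroid mean of 7.36, the other α-KG libraries 9.25 to 9.93. α-KG 2 had a skeletal muscle mean of 2.04, above 1.11 to 1.31. Water 3 had a T and NK cell mean of 1.496, above 1.12 to 1.16, and water 5 had a cholesterol synthesis mean of 3.63, above 3.13 to 3.24.

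α-KG 2 was the lowest of its group for Ccl2 at 1.89, Ctsc at 4.94, Ctss at 5.64 and Trim30a at 4.27, and α-KG 5 was the lowest for Pdk1 at 2.68. Water 3 was the lowest of its group for Cdk1 at 5.52, Tpx2 at 6.34, Rhag at 6.49 and Pcx at 4.19, and the highest for H2-DMa at 3.77 and Mrc1 at 2.59. Water 1 was the lowest for Npc2 at 5.28 and the highest for Tmem184a at 3.83, water 4 was the lowest for Xist at 8.12, and water 5 was the lowest for Trim30a at 3.71.

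Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, stood at 14.6 in α-KG 4, where the other α-KG libraries had 11.98 to 12.5. Over the 10 libraries its level followed that of CT010467.1, the ribosomal RNA locus, with Pearson's r = 0.987 and Spearman's rho = 0.988 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; 1 relation tested). Without the 2 libraries farthest from the median, r was 0.971. The median r of 16 other mitochondrial aminoacyl-tRNA synthetase genes with the same locus was 0.255. Ribosomal RNA counted under Lars2 may therefore account for its level, as a hypothesis, and no biological explanation was tested.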

How the results depend on the processing

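Alternatives chosen only after the data were seen were those with the protein-coding share or the monocyte mean as a covariate, without abundant non-coding RNAs, with protein-coding genes alone, without several libraries together, and DESeq2 with each library left out. Against 413 genes, DESeq2 called 1657, limma voom 267, voom with quality weights 2390, edgeR at an adjusted p under 0.10 1798, with a surrogate variable 161 and with the erythroid mean as a covariate 206. The edgeR count was 0 with the protein-coding share as a covariate (3457 genes at an unadjusted p under 0.05), without α-KG 1 and α-KG 4 (2426), without these and water 1 (1861) and with the monocyte mean as a covariate (186), fits that DESeq2 was not run on. Leaving out 1 library gave 0 (without water 1, water 2, water 4 or α-KG 4) to 2683 genes (without α-KG 2) with edgeR and 497 (without water 4) to 3616 (without α-KG 2) with DESeq2. All 413 genes kept their sign in these fits except with the monocyte mean, where 387 of 413 did; Vcan (-0.12), Ndrg1 (-0.0307), Trim30a (-0.00815) and Ccl4 (-0.0251) reversed among the genes named. That list holds genes of the 413, so this fit removes part of what it tests; otherwise the cause was not tested. Against 11 lists, 7 were called with a surrogate variable, 6 with the erythroid mean, 0 with an estimated correlation, 2 by fry, and 8 to 12 without 1 library. The adjusted p of the first component was 0.0476 with all genes and 0.0317 to 0.175 without 1 library. The other 65 values of these results lay within 1.5 times the count or kept their side of the threshold. In simulated data of this depth, spread and number of libraries, 8.66% of 1.5-fold changes were recovered, with 200 changed genes and genes varying independently. What depth alone limits was not tested.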

Other observations

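The gene groups in the next 2 paragraphs and the share of monocyte and macrophage genes above 0 were chosen for testing only after the data were seen. Camera was adjusted over the 9 groups, and its p-values for groups picked from these data are no separate support. The lysosome, complement, nonclassical monocyte and dendritic cell groups also share members with the monocyte or macrophage lists. Examples are Ctss, C1qa, Cx3cr1 and Irf8. Genes of antigen presentation by MHC class II had log2 fold changes above 0 in all 10 measured members, with a median of 1.20, which was 0.78 without α-KG 1, 0.70 with the erythroid mean as a covariate and 0.62 without α-KG 1 and α-KG 4. B cells also express these genes, and the B cell list mean was 4.52 in α-KG 1 and 2.63 to 3.44 in the other α-KG libraries. H2-DMb1, Ciita and H2-DMa rose (log2 fold changes 1.22, 1.64 and 0.89, adjusted p = 0.0358, 0.0489 and 0.0402), and Cd74 was at 1.10 (adjusted p = 0.0611). H2-DMa overlaps Brd2, and Ciita overlaps Dexi. Of 12 genes of the interferon-inducible p200 family, 7 rose, with a list median of 1.10 that was 0.71 to 1.26 over the alternatives. Among those that rose were Ifi211 (1.64 ± 0.26 SE, adjusted p = 0.0154) and Ifi204 (1.04 ± 0.21, adjusted p = 0.0278). The genes of this family are described as a group. These genes lie side by side on chromosome 1 and resemble each other, so counts assigned to single members are uncertain, and Ifi211 and Ifi203 overlap Mndal on the same strand. Of 24 lysosome genes 6 rose, with Naaa (1.21, adjusted p = 0.0154) and Ctsc (1.18, adjusted p = 0.0168) among them. Camera called these 3 lists (adjusted p = 4.52e-07, 2.10e-09 and 1.81e-06), with an adjusted p = 0.195, 0.159 and 0.195 once the correlation was estimated.

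Of 11 complement genes 2 rose, among them Cfb (1.33, adjusted p = 0.0416), and of 8 genes of GIMAP GTPases 2 rose, Gimap4 and Gimap7 (1.22 and 1.35, adjusted p = 0.0459 and 0.0489), the GIMAP median of 1.06 being 0.69 without α-KG 1 and 0.51 without α-KG 1 and α-KG 4. Of 16 genes of nonclassical monocytes 5 rose, among them Pou2f2 (1.24, adjusted p = 0.0274) and Adgre4 (1.45, adjusted p = 0.0421). All 57 measured replication-dependent histone genes had log2 fold changes below 0, with a median of -0.84, and 2 fell. Over the alternatives, the median of the histone genes was -0.99 to -0.51. Camera called these 4 lists (adjusted p = 1.37e-05, 0.000146, 1.37e-05 and 7.34e-19), with an adjusted p = 0.195, 0.206, 0.195 and 0.206 once the correlation was estimated. Of 16 dendritic cell genes 1 rose (camera adjusted p = 0.0146, and 0.376 with an estimated correlation), a call lost without α-KG 5, without α-KG 1 and α-KG 4, without these and water 1, and with the protein-coding share as a covariate. Of 16 mitochondrial aminoacyl-tRNA synthetase genes 0 changed in edgeR (camera adjusted p = 0.603). The bone collagen gene Col1a1, a member of the stromal list, was at -1.64 (adjusted p = 0.0577), with 69.0 ± 44.0 CPM in water and 22.03 ± 7.16 in α-KG (SD, n = 5).

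Monocyte and macrophage genes were higher in α-KG, with a median log2 fold change of 1.03 over the 31 members of both lists. Their median exceeded that of genes matched in GC content and length by 1.00, where the SE of their mean difference between libraries was 0.161, and stayed at 0.93 or above whichever library was left out, which argues against either as the whole source. With the protein-coding share as a covariate it was 0.83, and the mean over the same members was 0.747 higher in α-KG (SE between libraries 0.196). Both values were above the bound of 0.5 by more than this SE, which belongs to the mean, and both lists were still called by camera. The criterion written beforehand asked for more than the spread and gave no multiple, so it was met at 1 SE and not at 2 SE. The covariate shrank the median only from 1.03 to 0.83, which argues against a lower share of protein-coding counts as the whole source. A lower share stays open as part of the source. The 95% interval of the mean over the same members, 0.285 to 1.21, includes the bound. So does the interval without a covariate, so these intervals do not decide the question. Camera's part of the criterion carries little weight, because camera called at least as many lists in 69 of 100 splits of the libraries. A larger share of monocytes and macrophages and more RNA of these genes per cell cannot be told apart and both stay open; the 93.5% of members above 0 is the observation that raised them and tests neither.

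Cell cycle genes were lower in α-KG, with a median log2 fold change of -0.70 over 33 members. It was at most -0.54 whichever library was left out. This was beyond the bound of -0.3 by more than the SE between libraries of the list mean (0.216). That argues against a single library as the whole source. With the erythroid mean as a covariate the median was -0.48 and with the protein-coding share -0.77. The list mean differed by -0.509 (SE between libraries 0.174) and -0.855 (SE 0.329) in these fits. Medians and means were beyond the bound by more than these SEs, which belong to the means, and the list was still called by camera. The criterion written beforehand was therefore met only if its spread is read as 1 SE between libraries. The protein-coding share did not shrink the median, which argues against a lower share as the whole source. The erythroid mean did shrink it and passed narrowly on that reading, so fewer erythroid cells stay open as part of the source. The 95% intervals of the mean over the same members were -0.920 to -0.0977 and -1.63 to -0.0783. They include the bound, but so does the interval without a covariate, -1.37 to -0.163, so they do not decide the question. Camera's part of the criterion is weak, because the number of lists it called was reached in 69 of 100 splits. An effect of α-KG on proliferation was not tested apart from the groups. The criterion of the covariate tests, here and for the monocyte and macrophage genes, asked for more than the spread. It named neither the kind of spread nor a multiple. A first run used 2 SE between member genes, under which these explanations were excluded. The margin was then changed to 2 SE between libraries, under which they stay open, so what is said above at 1 SE depends on the margin. The margin for single libraries was set at 1 SE only after the values were seen, where none was written beforehand. At 2 SE a single library would stay open for the cell cycle genes.

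Grouping the libraries at random was tested with 100 splits of the 10 libraries into 5 and 5. For the 413 genes, the real split alone reached its count (1 of 100), and the highest of the others gave 0. Chance can be excluded for this count at 0.05 only if the 10 libraries are independent, which the labels do not show. The split test also cannot separate α-KG from other differences between the groups. The edgeR count itself was 0 without water 1, water 2, water 4 or α-KG 4. In these fits the smallest adjusted p of edgeR was 0.0512 to 0.0654. For the 11 lists, 69 of 100 splits reached as many, and the highest gave 19, so chance cannot be excluded for the number of lists.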
